A study of Homo sapiens with 29 samples.

How the data were processed

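The series holds 29 biopsy cores from transplanted kidneys, each measured on 1 Affymetrix whole-transcript microarray with total RNA labelled with biotin. Per the series' design text, all biopsies were near normal, with a chronic injury score of at most 3 and no diagnosis of rejection, glomerular disease or polyoma nephropathy. The labels put 16 cores in a control group with no exposure to an angiotensin-converting enzyme inhibitor (ACEI) or an angiotensin receptor blocker (ARB), 9 in an ARB group and 4 in an ACEI group. Exposure had lasted at least 6 months before the biopsy. The 13 ARB and ACEI arrays together are called exposed. Per the labels' protocols, a single core was kept in RNA preservative, renal tissue and glomeruli were verified under a dissecting microscope, and tissue from outside the kidney was removed.

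The deposited values are log2 expression values, 1 per probe set and array, which the authors made with RMA; RMA, oligo and limma are named without versions in the submitters' processing notes. RMA usually corrects background, normalizes arrays between each other by quantiles and summarises the probes of a probe set. That the scale is log2 was read from the values, which lie in a range usual for RMA. Which arrays were normalized together and which genome build was used are not given in the sources used here. With such a normalization, a shift in RNA level shared by most genes would be largely removed from these values, although array medians still ran from 6.48 to 6.59. A change in the cell types that make up a core changes the level of every gene those cells express. Arrays give no counts, so their number limits the precision.

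The table held 29096 probe sets. The probe annotation gave 1 gene symbol for 19460 of them and several for 1754, and 7882 were unnamed here. Through the gene ID, 19429 of the single-gene probe sets were found in the current RefSeq table (GRCh38.p14, used for names only), and 0 symbols changed. Left out before any test were 32 probe sets of Y-linked genes and X-inactivation transcripts, 14 of genes whose level is mainly set by a germline deletion or haplotype, and 17 of immunoglobulin and T cell receptor segments. A further 140 with several symbols, at least 1 of them of these classes, were left out of the test of all probe sets. Where a gene had more than 1 probe set (766 genes), the one with the highest mean over all arrays was kept, which left 18368 genes and no filter on dim ones. In the table, 968 probe sets shared all their values with another probe set. Some genes are not reported here.

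Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). The comparison of exposed with control used a fit of 2 groups over all 29 arrays, as in the series' design. ARB against control, ACEI against control and ARB against ACEI were contrasts of 1 fit of 3 groups, so that the 4 ACEI arrays shared the spread of all arrays. The labels describe each sample as a patient's biopsy, so the spread between arrays was taken as that between patients.

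Gene lists were fixed before the data were examined. They cover the renin-angiotensin system, aldosterone-responsive transport, vasoactive systems, matrix and TGF-beta, immune cells, interferon and cytokine responses, nephron segments, vessels, metabolism, stress, cell cycle, blood, fat and skeletal muscle, with 2 further lists by name, the ribosomal protein genes and the small nucleolar RNAs. Of the 33 fixed lists, 32 had at least 5 measured members, so 34 were tested; mitochondrially encoded transcripts had 0 measured members. The main list test was limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Beside it stand camera with an estimated correlation, fry, and a permutation test of the list score (two-sided, 100000 resamples, or an exact test over all splits for ACEI against control and ARB against ACEI). A list score is the mean over members of each array's log2 value minus the gene's mean over all arrays. Members of a list were also adjusted over the list alone.

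Genes are named by a rule fixed before the data were examined. For exposed against control they are the 10 genes per direction with the largest change among those past the threshold, filled up by smallest p where fewer passed, together with fixed renin-angiotensin genes and the members of smallest p of each list described. For the other comparisons they are the 5 genes of smallest p per direction, and any further gene named there was chosen after its values were seen.

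The fits were tested on simulated data with the real genes, means and spreads, in which 200 of 18368 genes were changed. For exposed against control, 85% of genes changed 1.5-fold and 94% of genes changed 2-fold were recovered. For ARB against control these were 79% and 95.5%, for ACEI against control 58.5% and 88.5%, and for ARB against ACEI 43.5% and 87.5%. Genes were drawn independently there, whereas genes in biopsy cores vary together.

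Alternatives fixed in advance were quantile normalization, median centring, removal of the dimmest 25% or 50% of genes, the mean of all probe sets, another eBayes prior, array weights, covariates for the depth of the core and for immune cells, the number in the titles as a block, other thresholds, other groups in the fit, and leaving out each array. Chosen after seeing the data were fits without 3 control arrays low in proximal tubule genes, fits without 4 arrays whose mean correlation with the others was under 0.95, and a covariate for fat and skeletal muscle. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.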

Results

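Gene expression was measured in 29 biopsy cores of near-normal kidney transplants, 16 from patients with no ACEI or ARB (control), 9 from patients on an ARB and 4 from patients on an ACEI. ACEI block the enzyme that makes angiotensin II, and ARB block its type 1 receptor. The series asks whether exposure to these drugs changed gene expression in the graft. The arrays had median log2 values from 6.48 to 6.59 and SDs from 1.87 to 2.13. The mean correlation of an array with the others, over 18368 genes, ran from 0.924 to 0.977. The 4 control arrays of replicates 1, 8, 14 and 15 had mean correlations under 0.95. In control replicates 8, 14 and 15 the proximal tubule list score was -1.92, -4.01 and -2.03, against 0.32 ± 0.22 (SD, n = 13) in the other controls and 0.29 ± 0.24 (SD, n = 13) in exposed arrays. Podocyte markers were also low in these 3 arrays, with scores from -0.83 to -0.64 against 0.11 ± 0.23 (SD, n = 13) in the other controls. Fat and skeletal muscle markers scored 2.88 in control replicate 8, 2.32 in control replicate 15 and 2.31 in ACEI replicate 2. They scored 1.41, 1.36 and 0.96 in ARB replicates 1, 3 and 4. The controls other than replicates 8, 14 and 15 scored -0.54 ± 0.13 (SD, n = 13).

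In exposed against control, no gene passed the threshold. The gene of smallest p among those higher in exposed cores was SNORD74, a small nucleolar RNA, at 11.52 ± 0.27 (SD, n = 13) against 10.86 ± 0.56 (SD, n = 16), a log2 change of 0.66 ± 0.16 (SE). It lay above the control mean in 13 of 13 exposed arrays. DCUN1D4, a neddylation cofactor, differed by 0.39 ± 0.10 (SE, 13 of 13 arrays), MSMO1, a sterol oxidase of cholesterol synthesis, by 0.42 ± 0.11 (12 of 13), and the translation initiation factor EIF5 by 0.35 ± 0.094 (11 of 13). The remaining genes higher in exposed were ZNF814 (0.53), NDFIP2 (0.34), MORN2 (0.44), the mitochondrial import receptor TOMM22 (0.38), TPRKB (0.35) and CAMK2N1 (0.20). The genes of smallest p among those lower in exposed began with the mitotic kinase PLK1, with a log2 change of -0.40 ± 0.10 (SE, 12 of 13 arrays below the control mean). C1QA, a chain of complement C1q made by macrophages, was 5.96 ± 0.26 (SD, n = 13) in exposed against 6.53 ± 0.50 (SD, n = 16) in control, a change of -0.57 ± 0.15 (SE, 13 of 13). UHRF1, which maintains DNA methylation at replication, differed by -0.33 and the actin-binding TMSB10 by -0.40. The other genes lower in exposed were CEMIP (-0.27), the G protein subunit GNAI2 (-0.26), ST6GALNAC6 (-0.25), SAE1 (-0.21), OS9 (-0.19) and TBCB (-0.23).

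All 20 of these genes had an adjusted p of 0.649 in limma, the smallest of the comparison, so none was separated from the spread between patients after correction. At an unadjusted p under 0.05, limma gave 1320 genes, 481 higher and 839 lower in exposed, where chance would give 918.4. With each array centred on its median the split turned to 711 higher and 539 lower. Of the 1320 genes, 33 were higher and 8 lower by at least 1.5-fold. The 95% confidence interval of a gene's change reached 0.18 log2 to either side at the median gene. Without control replicates 8, 14 and 15, again 0 genes passed and 1564 had an unadjusted p under 0.05.

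**Figure D1:**
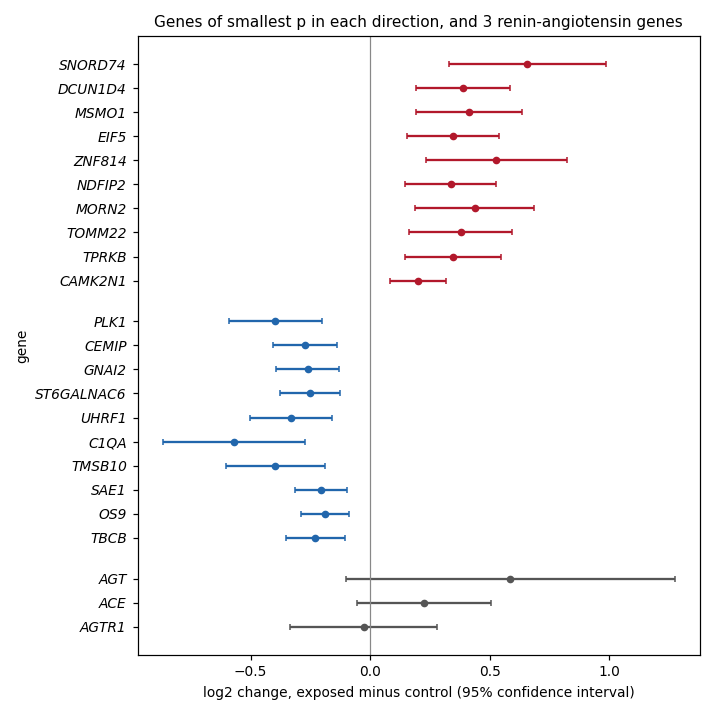
Log2 change of each named gene in exposed (n = 13) minus control (n = 16) arrays, with points for the estimate and bars for the 95% confidence interval from limma. Red points are the 10 genes of smallest p among those higher in exposed, blue points the 10 among those lower, and grey points are AGT, ACE and AGTR1, whose intervals include 0; no gene passed after correction over all genes.

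Of 16 measured genes of the renin-angiotensin system, the pathway the drugs act on, 0 passed when adjusted over the list alone and 0 over all genes. AGT, which encodes angiotensinogen, was 9.78 ± 0.35 (SD, n = 13) in exposed against 9.19 ± 1.25 (SD, n = 16) in control, a change of 0.59 ± 0.34 (SE, adjusted p = 0.719 in limma). Without control replicates 8, 14 and 15 the AGT change was 0.074 ± 0.15, and without control replicate 14 alone it was 0.37. ACE, the target of ACEI, differed by 0.23 ± 0.14 (SE) and by 0.067 without those arrays. AGTR1, the receptor that ARB block, differed by -0.027 ± 0.15 (SE, adjusted p = 0.968), and by 0.088 without those arrays. CTSG had the smallest p of the list, with a change of -0.15 ± 0.063 (SE) and an adjusted p of 0.328 over the list alone. MME, which encodes neprilysin, differed by 0.73 ± 0.41 (SE), by 0.47 without control replicate 14 and by 0.067 without those 3 arrays. As a list, these genes averaged 0.18 higher in exposed (camera adjusted p = 0.0564, and adjusted p = 0.582 with an estimated correlation), and 0.0056 without those arrays. The aldosterone-responsive sodium transport list averaged 0.050 higher (camera adjusted p = 0.0501), with 0 of 17 genes past the threshold adjusted over the list alone. Among its members SGK1, a kinase induced by mineralocorticoids, differed by 0.19 ± 0.10 (SE) and HSD11B2, which inactivates cortisol, by -0.28 ± 0.15. Genes of kinins, endothelin, nitric oxide and prostaglandins averaged 0.040 higher (camera adjusted p = 0.26), with PTGS2, or cyclooxygenase 2, at 0.32 ± 0.15 and 0 of 21 past the threshold adjusted over the list alone. Without control replicates 8, 14 and 15 these last lists averaged 0.098 and 0.097 and passed the preset test (camera adjusted p = 0.00267 and 0.027, and adjusted p = 0.387 with an estimated correlation for both).

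T cell, macrophage, neutrophil and interferon lists had lower means in exposed than in control. The preset camera test passed 14 of 34 lists, 6 higher and 8 lower. T cell markers averaged -0.31, with all 20 members lower (camera adjusted p = 9.19e-06, and adjusted p = 0.614 with an estimated correlation). None of the 20 passed when adjusted over the list alone, and the members of smallest p were the surface receptor CD5 (-0.32), the co-stimulator ICOS (-0.40) and the kinase LCK (-0.23). Macrophage and monocyte markers averaged -0.25, with 15 of 17 lower (camera adjusted p = 0.000161, and adjusted p = 0.614 with an estimated correlation). Of these, 4 fell when adjusted over the list alone, and 0 over all genes. They were the C1q chains C1QA (-0.57), C1QB (-0.60) and C1QC (-0.54) and the lipopolysaccharide receptor CD14 (-0.34). Type I interferon-inducible genes averaged -0.26, with 20 of 21 lower and 0 passed adjusted over the list alone (camera adjusted p = 0.000596, and adjusted p = 0.676 with an estimated correlation). IFIT2 (-0.36) and MX2 (-0.51), both antiviral effectors, had the smallest p there. Interferon-gamma-inducible genes averaged -0.27, with 17 of 17 lower and 0 passed adjusted over the list alone (camera adjusted p = 0.00453, and adjusted p = 0.676 with an estimated correlation). The peptide transporter TAP1 differed by -0.43 and the immunoproteasome subunit PSMB10 by -0.23. Neutrophil markers averaged -0.12, with 9 of 10 lower and 0 passed adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.582 with an estimated correlation).

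None of these immune and interferon calls held with fry either (adjusted p = 0.513 for each). The permutation test of the list score gave p = 0.117 for T cells, 0.0977 for macrophages and 0.0427 for neutrophils, and 0.598 for each after adjustment over 34 lists. The T cell score was -0.17 ± 0.47 (SD, n = 13) in exposed and 0.14 ± 0.55 (SD, n = 16) in control, so the difference was smaller than the spread within either group. With control replicates 8, 14 and 15 left out, the mean changes of the T cell and macrophage lists were -0.41 and -0.32. Those arrays averaged -0.27 for T cell and -0.23 for macrophage markers, against 0.24 and 0.19 in the other controls. Their removal could therefore only widen both changes. The interferon-gamma call was lost without control replicate 6 (mean -0.18), and the type I interferon mean was -0.14 without control replicate 10. Type I interferon scores were 1.29 and 1.87 in control replicates 5 and 10, which raised the control mean of 0.12. The neutrophil call was lost without any 1 of control replicates 1, 2, 4 and 6, ACEI replicates 1 and 2 and ARB replicates 5, 7 and 9, with means from -0.11 to -0.095.

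**Figure D2:**
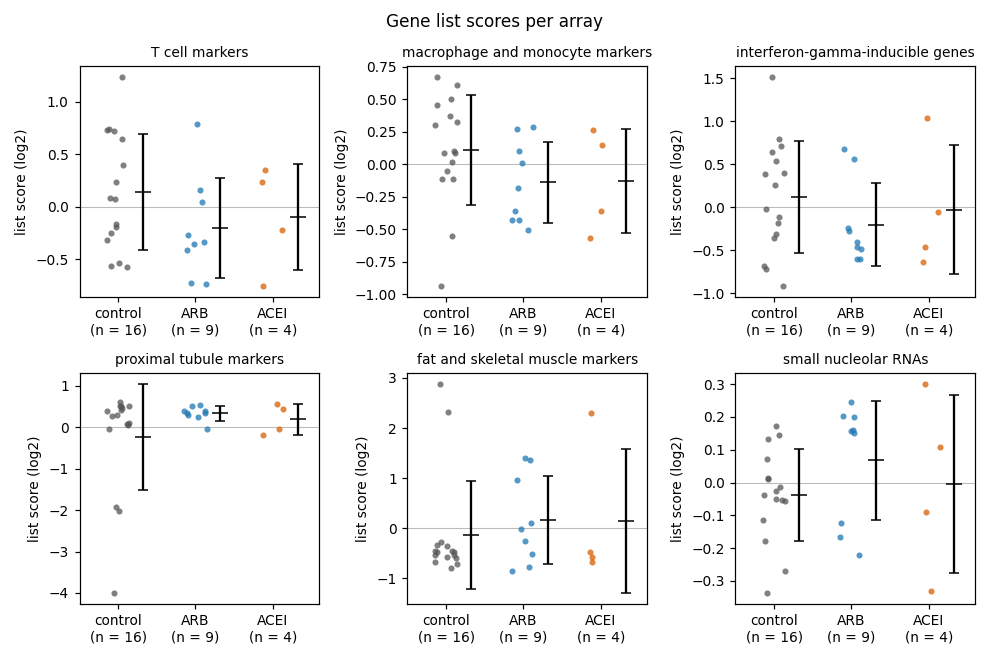
Score of 6 gene lists in each array (log2, mean over members relative to the mean of all arrays) for the 16 control, 9 ARB and 4 ACEI arrays; points are arrays, and the black mark and bar are the group mean and SD. T cell and macrophage scores overlap between all groups, 3 control arrays lie at -1.92 or lower for proximal tubule markers, and 2 control arrays and 1 ACEI array lie above 2 for fat and skeletal muscle markers. ARB replicates 1, 3 and 4 lie at 1.41, 1.36 and 0.96 for fat and skeletal muscle markers, above the other ARB arrays.

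Among nephron lists, proximal tubule markers averaged 0.53 higher in exposed, with 21 of 21 members higher (camera adjusted p = 2.65e-07, and adjusted p = 0.582 with an estimated correlation). None passed adjusted over the list alone. The phosphate transporter SLC34A1 differed by 0.97 ± 0.53 (SE), the creatine synthesis enzyme GATM by 0.52 ± 0.22 and the bicarbonate transporter SLC4A4 by 0.44 ± 0.25, or 0.28 without control replicate 14. When control replicates 8, 14 and 15 were left out, the list's mean change was -0.029 and the call was lost, though those arrays were picked by this score, and without control replicate 14 alone it was 0.28. Loop of Henle and distal tubule markers averaged 0.24 higher, with 12 of 13 members higher and 0 passed adjusted over the list alone (camera adjusted p = 0.00453, and adjusted p = 0.582 with an estimated correlation). CLDN16, a tight junction protein of the thick ascending limb, differed by 0.44 ± 0.21, and the calcium-binding CALB1 by 0.98 ± 0.63, which was 0.56 without control replicate 15 and turned to -0.095 without those 3 arrays. Tubular injury genes averaged -0.19, with 17 of 21 lower and 0 passed adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.676 with an estimated correlation). Their members of smallest p were KRT18 (-0.33), LTF (-0.71) and SOX9 (-0.19). Lower in exposed was also the extracellular matrix list, by -0.20 on average with 22 of 28 members lower (camera adjusted p = 0.00453, and adjusted p = 0.676 with an estimated correlation). Its members LOXL1 (-0.19), COL5A1 (-0.23) and COL3A1 (-0.60) had the smallest p, and 0 passed adjusted over the list alone. The matrix call was lost without control replicate 4 (mean -0.16) or control replicate 8 (-0.15). The tubular injury call was lost without any 1 of control replicates 1, 2, 4, 8, 9 and 16, ACEI replicates 1 and 2 and ARB replicates 1, 5 and 6, with means from -0.19 to -0.12 (without control replicate 8). Basement membrane genes averaged -0.086 (camera adjusted p = 0.0838), with COL4A2 at -0.29 ± 0.10 (SE), COL4A1 at -0.30 ± 0.10 and 0 of 17 past the threshold adjusted over the list alone.

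Cell cycle genes averaged -0.14 in exposed, with 14 of 17 lower (camera adjusted p = 0.000161, and adjusted p = 0.582 with an estimated correlation). PLK1 fell when adjusted over the list alone (adjusted p = 0.0039 in limma), which leaves the number of lists uncorrected, and it did not pass over all genes. The mitotic checkpoint kinase BUB1 (-0.25) and the survival factor BIRC5 (-0.20) did not pass over the list alone. Small nucleolar RNAs averaged 0.082 higher, with 119 of 192 higher and 0 passed adjusted over the list alone (camera adjusted p = 9.19e-06, and adjusted p = 0.582 with an estimated correlation). Hypoxia-inducible genes averaged 0.054 higher (camera adjusted p = 0.0339, and adjusted p = 0.582 with an estimated correlation), with the collagen hydroxylase P4HA1 at 0.28 and the oxygen sensor EGLN3 at 0.19. Fatty acid oxidation genes averaged 0.071 higher (camera adjusted p = 0.0343, and adjusted p = 0.676 with an estimated correlation) with HADHA at 0.17 and CPT1A at -0.15. Fat and skeletal muscle markers averaged 0.28 higher (camera adjusted p = 0.0343, and adjusted p = 0.676 with an estimated correlation), and the fat marker FABP4 differed by 0.63 ± 0.38 (SE). In these last 3 lists 0 members passed adjusted over the list alone. The hypoxia call was lost without any 1 of control replicates 1, 2, 4 and 9 and ARB replicates 5 and 7, with means down to 0.035 (without control replicate 1) and 0.017 (without ARB replicate 7). The fatty acid oxidation call was lost without any 1 of control replicates 1, 4, 8, 14, 15 and 16, ACEI replicates 1 and 2 and ARB replicates 1, 2, 4, 5 and 9, with means down to 0.042 (without control replicate 1) and 0.043 (without ACEI replicate 1). The fat and skeletal muscle call was lost without any 1 of control replicates 2 to 7, 9, 10, 12 and 16, ARB replicates 1 and 3 to 6 and ACEI replicate 2, with means down to 0.10 (without ACEI replicate 2) and 0.18 (without ARB replicate 1 or 3). Its mean was 0.48 without control replicate 8 and 0.45 without control replicate 15. The preset test passed 8 lists without control replicate 4 and 9 without ARB replicate 5, in place of 14. In the fit without control replicates 8, 14 and 15, the preset test passed 16 lists and none held with an estimated correlation (smallest adjusted p = 0.387). In that fit the fat and skeletal muscle mean was 0.69 and the hypoxia mean 0.11, and the fatty acid oxidation call was lost (mean 0.0062). Control replicates 8 and 15 were the controls highest in fat and skeletal muscle markers (2.88 and 2.32), so the larger mean follows from the choice of arrays. The remaining controls averaged -0.54 for these markers and the exposed arrays 0.16, so the groups of that fit differed in them.

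The other lists did not pass in exposed against control. Their mean log2 changes were 0.039 for glucocorticoid-responsive genes, -0.014 for TGF-beta signalling, -0.13 for NK and cytotoxic cells, 0.11 for B and plasma cells and -0.062 for mast cells. Inflammatory cytokines and NF-kB targets averaged -0.084, complement and coagulation -0.073 (with C3 at -0.76 ± 0.32, SE), and immediate early genes -0.087. Collecting duct markers averaged -0.022, podocyte markers 0.10, endothelial markers -0.026 and smooth muscle, pericyte and mesangial markers -0.088. Respiratory chain subunits averaged -0.0089, antioxidant genes -0.0037, blood and platelet transcripts -0.023 and ribosomal protein genes -0.025. For B and plasma cells the mean was positive and the median -0.034, and JCHAIN, the immunoglobulin joining chain of plasma cells, differed by 1.49 ± 0.59 (SE). For TGF-beta signalling, collecting duct, endothelial and respiratory chain genes the mean was negative and camera's direction was up, and for antioxidant genes the mean and the median differed in sign. The means of TGF-beta signalling, respiratory chain, antioxidant and blood lists changed sign under quantile normalization or median centring. Without control replicates 8, 14 and 15, the means of collecting duct (0.031), podocyte (-0.049), endothelial (0.039) and smooth muscle (0.055) lists changed sign. So did those of TGF-beta signalling (0.055) and respiratory chain (0.014). With control replicates 8, 14 and 15 left out, NK cell and antioxidant lists passed the preset test (means -0.19 and -0.096, camera adjusted p = 0.0107 and 0.0333, and adjusted p = 0.736 and 0.602 with an estimated correlation).

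In ARB against control (9 and 16 arrays), genes lower in ARB cores were led by SMOX, which oxidizes spermine, with a log2 change of -0.41 ± 0.095 (SE, 9 of 9 arrays below the control mean). UHRF1 differed by -0.39, CEMIP by -0.31, PLK1 by -0.42 and the metalloprotease ADAM19 by -0.36. Higher in ARB cores were MAJIN (0.37), MSMO1 (0.44), DCUN1D4 (0.38), SNORD74 (0.61) and ZNF814 (0.54). T cell markers averaged -0.35, with 20 of 20 lower (camera adjusted p = 7.03e-06, and adjusted p = 0.517 with an estimated correlation). Immediate early genes, which respond within minutes to stress, averaged -0.15, with 14 of 16 lower (camera adjusted p = 0.0024, and adjusted p = 0.456 with an estimated correlation). Inflammatory cytokines and NF-kB targets also averaged -0.15, with 17 of 20 lower (camera adjusted p = 0.00174, and adjusted p = 0.456 with an estimated correlation). Renin-angiotensin genes averaged 0.21 higher, with 12 of 16 higher (camera adjusted p = 0.0409, and adjusted p = 0.456 with an estimated correlation). In these 4 lists 0 genes passed adjusted over the list alone. Elsewhere, PLK1 fell when adjusted over the cell cycle list alone (adjusted p = 0.0086 in limma). KRT18, a keratin of injured tubules chosen after its values were seen, fell when adjusted over the tubular injury list alone (-0.43, adjusted p = 0.0269 in limma).

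Over all 18368 genes, 0 passed in limma in ARB against control, with a smallest adjusted p of 0.802. At an unadjusted p under 0.05 there were 1011, 348 higher and 663 lower, and with each array centred on its median 506 higher and 475 lower. The preset camera test passed 19 lists, 8 higher and 11 lower, and none held with an estimated correlation (smallest adjusted p = 0.456) or with fry (smallest adjusted p = 0.444). When control replicates 8, 14 and 15 were left out, the renin-angiotensin mean was 0.031 and the proximal tubule mean 0.015, in place of 0.57, and both calls were lost.

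In ACEI against control (4 and 16 arrays), the genes of smallest p among those higher in ACEI cores were the small Cajal body RNA SCARNA16, with a log2 change of 0.48 ± 0.10 (SE, 4 of 4 arrays above the control mean), and the proteasome subunit PSMA1, with 0.58 ± 0.14 (4 of 4). EIF5 (0.52), SNORD43 (0.74) and OXSM (0.49) were also higher. Lower were TTC5 (-0.39), the macrophage folate receptor FOLR2 (-0.65), ANKRD6 (-0.32), ADAD2-AS1 (-0.61) and UNC45A (-0.31). Type I interferon-inducible genes averaged -0.40, with 21 of 21 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 3.52e-05, and adjusted p = 0.901 with an estimated correlation). Scores of this list were 1.29 and 1.87 in control replicates 5 and 10, which raised the control mean of 0.12. In ACEI replicates 1 to 4 they were -0.46, -0.49, -0.34 and 0.13. Macrophage markers averaged -0.24 (camera adjusted p = 0.00518, and adjusted p = 0.901 with an estimated correlation). Among them C1QB (-0.77) and C1QA (-0.67), chosen after their values were seen, fell when adjusted over the list alone (adjusted p = 0.0418 in limma for both). Macrophage scores in ACEI replicates 1 to 4 were -0.36, -0.57, 0.15 and 0.26, against a mean of 0.11 in control. The lower mean thus rested on ACEI replicates 1 and 2. SCARNA16 passed adjusted over the small nucleolar RNAs alone (adjusted p = 0.0154 in limma). B and plasma cell markers averaged 0.28 higher, with 12 of 15 higher and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00619, and adjusted p = 0.901 with an estimated correlation).

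Over all genes, 0 passed in limma in ACEI against control, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 676, 323 higher and 353 lower, and with each array centred on its median 500 higher and 242 lower. The preset camera test passed 7 lists, and none held with an estimated correlation (smallest adjusted p = 0.901) or with fry (smallest adjusted p = 0.944). Without ACEI replicate 3 or without ACEI replicate 4 it passed 14. In the fit without control replicates 8, 14 and 15, the B and plasma cell call was lost (mean 0.20), and the proximal tubule call turned from a mean of 0.43 to one of -0.13 (camera adjusted p = 0.0436, and adjusted p = 0.796 with an estimated correlation).

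The drug classes were compared directly in ARB against ACEI (9 and 4 arrays). Lower in ARB were the transcription factor GATA6, at 7.54 ± 0.095 (SD, n = 9) against 7.91 ± 0.23 (SD, n = 4), KAAG1 (-0.39, and -0.24 without ACEI replicate 3), TSPAN11 (-0.50), VAMP5 (-0.34) and RPL29 (-0.41). Higher in ARB were PRKXP1 (0.75), NUDCD2 (0.38), RPSA2 (0.66), the potassium channel KCNJ16 (0.40) and CCDC90B (0.40). AGTR1, shown here after its values were seen, was 8.02 ± 0.34 (SD, n = 9) in ARB and 7.44 ± 0.15 (SD, n = 4) in ACEI, a difference of 0.59 ± 0.22 (SE) that did not pass adjusted over the renin-angiotensin list alone (adjusted p = 0.196 in limma). Immediate early genes averaged -0.21 in ARB against ACEI, with 13 of 16 lower (camera adjusted p = 2.68e-07, and adjusted p = 0.247 with an estimated correlation). The difference rested on ACEI replicates 3 and 4, as scores in ACEI replicates 1 to 4 were -0.11, -0.14, 0.42 and 0.22, against a mean of -0.11 in ARB. The members of smallest p were the stress-induced transcription factors NR4A3 (-0.34) and ATF3 (-0.25), chosen after their values were seen, and 0 passed adjusted over the list alone. Inflammatory cytokines and NF-kB targets averaged -0.22, with 18 of 20 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 9.83e-06, and adjusted p = 0.294 with an estimated correlation). Among them the chemokine CCL20, chosen after its values were seen, differed by -0.48, and by -0.24 without ACEI replicate 3. Scores of this cytokine list in ACEI replicates 1 to 4 were -0.26, -0.22, 0.47 and 0.44, against a mean of -0.11 in ARB. Only ACEI replicates 3 and 4 thus lay above the ARB mean.

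Over all genes, 0 passed in limma in ARB against ACEI, with a smallest adjusted p of 0.999945. At an unadjusted p under 0.05 there were 308, of which 207 were lower, fewer than the 918.4 that chance gives. That number was 691 without ACEI replicate 1, 176 without ACEI replicate 4 and 584 when the control arrays were left out of the fit. The preset camera test passed 10 lists, 3 higher and 7 lower, and 17 without ACEI replicate 2 or 6 without ACEI replicate 3. None held with an estimated correlation (smallest adjusted p = 0.247) or with fry (smallest adjusted p = 0.759), and an exact permutation test of the immediate early score gave p = 0.0503, or 0.884 after adjustment over 34 lists.

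Across genes, the ARB and ACEI changes against the same controls correlated with r = 0.549 (genes are not independent replicates), and 67.4% of genes had differences of the same sign. Both changes share the controls, which alone can raise r. Simulated arrays with no changed group, controls included and genes drawn independently, gave a mean r of 0.262. Their mean covariance was 0.00694, against the observed 0.0133. Real genes vary together, which this simulation leaves out. Random regroupings of the 29 arrays gave r from -0.21 to 0.74, and 11 of 100 gave at least the observed value. With the controls split into 8 for each drug class, the mean r over 100 splits was 0.155, with a range from -0.14 to 0.45. Without ACEI replicate 1, r was 0.331. A shared change of the drug classes was therefore not separated from the shared controls and the spread between arrays.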

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

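The tests without the 3 control arrays low in proximal tubule genes, and that with the array median as a covariate, were chosen after the result was seen, as was the use of median centring, an alternative fixed in advance, to test the small nucleolar RNA shift.

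T cell and macrophage lists were lower in exposed cores, by -0.28 ± 0.16 (SE) for the mean of both list scores. With a cortex score as a covariate, a test of the depth of the core, the shift was -0.373 ± 0.149 (SE). The 3 control arrays low in proximal tubule genes averaged -2.65 for those markers, against 0.32 in the other controls. Such a score thus mostly sets these arrays apart, so depth among the other arrays stays open. Without these 3 arrays the shift was -0.366 ± 0.155 (SE), which argues against them as its source. They averaged -0.27 for T cell and -0.23 for macrophage markers, against 0.24 and 0.19 in the other controls. Leaving them out could therefore only widen the shift. Chance stays open, since the permutation test of the list score gave p = 0.117 for T cells and 0.0977 for macrophages, and 0.598 for both after adjustment over 34 lists. Also open, and untested, are an effect of the drugs, which the design names, and a difference between patients that goes with the prescription.

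Proximal tubule markers were higher in exposed cores, by 0.53 ± 0.36 (SE). Without control replicates 8, 14 and 15 it was -0.029 ± 0.090 (SE), but those arrays were picked by this same score, so the test decides nothing. In them the collecting duct score lay 0.285 above the other controls (SD 0.226, n = 13) and podocyte scores averaged -0.70 against 0.11, so more medulla and less cortex in these cores is a candidate explanation. Other lists do not speak for it alone, since endothelial scores averaged 0.30 against -0.054 and smooth muscle scores 0.66 against -0.10. Loop of Henle and distal tubule scores averaged -0.32 against -0.059, but were -1.18 in control replicate 8, 0.17 in replicate 14 and 0.042 in replicate 15. Fat and skeletal muscle scores were 2.88 in control replicate 8 and 2.32 in replicate 15. They were -0.27 in replicate 14, the array lowest in proximal tubule genes. An effect of the drugs stays open and untested.

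Small nucleolar RNAs were higher in exposed cores, by 0.082 ± 0.064 (SE). With each array's median log2 value as a covariate the shift was 0.016 ± 0.054 (SE), but centring each array on its median left it at 0.098 ± 0.061 (SE). After quantile normalization it was 0.098 ± 0.066 (SE). Both last values lie between 1 and 2 SE from 0, so a difference in signal distribution or normalization between arrays cannot be told apart from the groups. An effect of the drugs stays open and untested.

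Other splits of the same arrays, 100 for each result, gave these counts. For genes past the adjusted threshold, where limma's count was 0 in each comparison, 100 of 100 splits gave at least as many, as any split must, so this says nothing about chance. Another split gave up to 1 gene for exposed against control, 5 for ARB against control, 2540 for ACEI against control and 35 for ARB against ACEI. For renin-angiotensin genes adjusted over the list alone, 100 of 100 splits gave at least the 0 genes seen, which again says nothing, and another split up to 3. At an unadjusted p under 0.05, as many genes came from 27 splits for exposed against control (1320, up to 3524 in another split) and 24 for ARB against control (1011, up to 2915). For ACEI against control they came from 60 (676, up to 6019) and for ARB against ACEI from 63 (308, up to 2055). As many lists came from 29 splits for exposed against control (14, up to 21), 6 for ARB against control (19, up to 23), 88 for ACEI against control (7, up to 22) and 70 for ARB against ACEI (10, up to 23). Chance is not excluded for these counts at an unadjusted p or for these lists. Splits that call several times the real count point to a structure of the arrays other than the groups.

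The drug classes differed in 10 lists by camera's preset test of ARB against ACEI, and none of these differences held with an estimated correlation (adjusted p from 0.247 to 0.853). Lower in ARB on the log2 scale were TGF-beta signalling (-0.11), NK and cytotoxic cells (-0.20), B and plasma cells (-0.25), inflammatory cytokines and NF-kB targets (-0.22), tubular injury genes (-0.23), immediate early genes (-0.21) and ribosomal protein genes (-0.064). In the TGF-beta, NK, cytokine and tubular injury lists, ACEI replicates 1 and 2 scored below the ARB mean and replicates 3 and 4 above it. Tubular injury scores in ACEI replicates 1 to 4 were -0.40, -0.65, 0.94 and 0.33, against a mean of -0.18 in ARB. NK scores there were -0.33, -0.32, 0.24 and 0.69, against -0.13. Higher in ARB were type I interferon-inducible genes (0.21), collecting duct markers (0.17) and small nucleolar RNAs (0.071). Small nucleolar RNA scores in ACEI replicates 1 to 4 were 0.30, 0.11, -0.33 and -0.091, on both sides of the ARB mean of 0.067. Collecting duct scores were 0.25, -0.023, -0.27 and -0.46, against an ARB mean of 0.039.

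Single ARB or ACEI arrays stood apart from the rest of their group in 8 of 158 combinations of group and list or gene, where chance gives about 7.9. The control arrays were not tested in this way, so the count says nothing about them. Among controls, 3 arrays scored from -4.01 to -1.92 for proximal tubule markers. The gap to the nearest array, as a share of the group's range, was 0.542 for type I interferon-inducible genes and 0.78 for hypoxia-inducible genes in ARB arrays, both from a high array. Among ACEI arrays it was 0.839 for endothelial markers, 0.917 for cell cycle genes and 0.93 for fat and skeletal muscle markers, each from a high array. For single genes it was 0.541 for TTC5 in ARB arrays, from a low array. In ACEI arrays it was 0.839 for ANKRD6, from a low array, and 0.863 for ADAD2-AS1, from a high array.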

How the results depend on the processing

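The fits without the 3 control arrays low in proximal tubule genes, without the 4 arrays of mean correlation under 0.95 and with a fat and skeletal muscle covariate were chosen after the result was seen. The count of genes past the adjusted threshold was 0 in limma in all 4 comparisons and under every refit. For exposed against control the smallest adjusted p ran from 0.0833 to 0.863 over the alternatives and the count at an unadjusted p under 0.05 from 750 with the lowest 50% of genes left out to 2731 with array weights, and from 986 to 1808 when each array was left out. Counting genes at an unadjusted p under 0.05 in place of the adjusted one gave 1320, 1011, 676 and 308 for exposed, ARB and ACEI against control and ARB against ACEI, and with at least 1.5-fold 41, 35, 38 and 13, by construction of the looser threshold. The lists passed fell from 14, 19, 7 and 10 to 0 in all 4 comparisons with an estimated correlation, which for camera replaces the preset 0.01, and with fry, where the cause was not tested. Genes in the lowest 50% had no value in the fits that left them out.

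With the lowest 50% of genes left out, so that fewer members were tested, 9 lists passed for exposed against control, 2 for ACEI against control and 6 for ARB against ACEI. Array weights gave 9 for exposed, 12 for ARB against control and 6 for ARB against ACEI. The T cell and macrophage covariate gave 2 for exposed and 3 for ARB against control. The number in the titles as a block gave 5 for ARB against ACEI. Apart from the T cell and macrophage covariate, which removes immune differences by construction, the cause was not tested for these. With each array left out, the lists ran from 8 to 18 for exposed against control, 14 to 21 for ARB, 5 to 14 for ACEI and 6 to 17 for ARB against ACEI. The call ended in 2 of 29 such fits for extracellular matrix, 9 for neutrophil markers, 1 for interferon-gamma-inducible genes, 11 for tubular injury genes, 6 for hypoxia-inducible genes, 13 for fatty acid oxidation and 16 for fat and skeletal muscle markers, and in 0 for the remaining 7 lists. The correlation of ARB and ACEI changes ran from 0.331 to 0.615 with each array left out, and was 0.155 with the controls split, which removes the shared controls.

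Of 116 named genes' results 113 were never reversed. Most of these genes were chosen by small p in these same arrays, so a kept sign follows largely from that choice. The same holds for the 14 lists, chosen for passing the preset test, of which 10 were never reversed. Among these, macrophage markers mirrored T cell markers under the covariate made from both, and fat and skeletal muscle markers had no value under their own covariate. The AGTR1 difference in exposed turned to 0.050 with array weights, 0.039 with the cortex covariate, 0.020 with the block, 0.088 without the 3 controls and 0.039 without the 4 arrays, and ran from -0.086 to 0.044 with each array left out. T cell markers turned to 0.015 and interferon-gamma-inducible genes to 0.082 with the T cell and macrophage covariate. CALB1 was -0.095 without the 3 controls and -0.15 without the 4 arrays, proximal tubule markers -0.029 and -0.048, and without the 4 arrays SLC4A4 was -0.0050 and fatty acid oxidation -0.035. The 3 controls were picked by proximal tubule markers, so that reversal follows from the choice. For AGTR1 the cause was not tested, and for the others fewer arrays or the covariate changed the value. Arrays of the same number in the titles were not alike, with a mean correlation of 0.021 over 9 pairs of control and ARB, -0.099 over 4 of control and ACEI and -0.054 over 4 of ARB and ACEI. The number of arrays limits the precision.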

Other observations

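The genes of this part were chosen after their values were seen, in the fit of exposed against control without control replicates 8, 14 and 15. For fat and skeletal muscle markers the controls of this fit averaged -0.54 and the exposed arrays 0.16. Among the 20 genes of smallest p, C1QA differed by -0.65 ± 0.12 (SE), C1QB by -0.72 ± 0.16 and C1QC by -0.65 ± 0.17, which together encode C1q. The macrophage folate receptor FOLR2 differed by -0.44 ± 0.11 and C3, the central complement protein, by -1.09 ± 0.22. PATL2 (-0.38), IGFLR1 (-0.40) and SPATA6 (0.31) also had a smaller p than FOLR2. The macrophage list averaged -0.32 in this fit (camera adjusted p = 2.4e-08, and adjusted p = 0.387 with an estimated correlation). The control arrays left out averaged -0.23 for macrophage markers, against 0.19 in the other controls. The fit could therefore only widen the mean difference of that list. The complement and coagulation list did not pass, at -0.11 (camera adjusted p = 0.382, and adjusted p = 0.874 with an estimated correlation). Lower were also GSDMD (-0.24), which encodes a pore-forming protein of pyroptosis, and POR (-0.27), the electron donor of microsomal P450 enzymes. Higher were SNORD74 (0.74), the autophagy gene ATG10 (0.41) and NDUFAF4 (0.36), an assembly factor of respiratory complex I. In limma 0 genes passed in this fit (smallest adjusted p = 0.221, and from 0.0833 to 0.863 over the alternatives), and 1564 had an unadjusted p under 0.05.

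Of the probe sets without a single gene name, 9496 were tested within a fit of 28893 probe sets in exposed against control, and 140 were left out beforehand. None of them passed in limma (smallest adjusted p = 0.36), and 783 had an unadjusted p under 0.05, where chance would give 474.8. Other splits of the arrays were not run for this count. For the named genes, 27 of 100 splits, the real one included, gave at least the 1320 seen, and another split up to 3524. The excess is thus not separated from chance.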
